A study of Mus musculus with 15 samples.

How the data were processed

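RNA of mouse brains was compared on 15 arrays with 2 colours each. Per the labels, channel 1 held a pool of 4 wild-type brains and channel 2 RNA of 5 homozygous O377 brains, with dyes exchanged on 8 arrays. Arrays are numbered 1 to 15 in accession order, and these numbers did not pair or group arrays in the model reported. The labels do not say which brain is on which array, or whether the 5 RNAs were pooled, so p-values measure the spread between arrays, which may be technical.

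The authors deposited 1 log ratio per probe and array, here taken as log2. The base is not stated in the sources used here. It was taken as 2 because the largest value in size, 12.33, would exceed by 1.24 the natural log of the largest ratio that a scanner of 16 bits gives. Medians of the deposited columns lay between -0.00618 and 0.0165, so arrays had been centred before deposit, by a method not given in the sources used here. Those of arrays 1 to 15 were -0.00118, -0.00567, -0.00595, -0.00356, 0.00286, -0.00124, 0.000661, -0.00161, 0.0165, 0.00144, 0.00556, -0.000916, -0.00618, 0.00218 and 0.00243. The direction of the ratio, mutant over wild type or Cy5 over Cy3, is not stated either. Between 38.8% and 52% of probes had a value per array, so spots had been filtered by a rule that is not given in the sources used here, and 4027 of 20205 probes had no value on any array. Interquartile ranges ran from 0.386 to 0.892, widest on arrays 10 (0.892) and 9 (0.731), and 14 to 115 values per array lay beyond 4 in size. Scanner intensities were not analysed here, so a filtered spot cannot be told from a dim one. The number of arrays limits the precision, and the median standard error of a component was 0.0897.

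Probes were named through the platform's annotation table, with symbols updated through gene identifiers to the GRCm38.p6 reference. Of all probes, 11723 had 1 gene symbol, 806 several and 7676 none. Of the 8058 tested probes these numbers were 4775, 342 and 2941, for 4372 distinct genes. Probes with several or no symbols were counted and not named. No genome build is given for the arrays, so no coordinates are printed, and the reference served only for names and for which genes lie near each other.

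Values were used as deposited. A probe was tested if it had values on at least 4 arrays of each dye orientation. A linear model in limma 3.58.1 (R 4.3.3) with a term for dye orientation gave a shared component, the mean of both orientation means, and a dye-switching component, the difference of the orientation means (mutant in Cy5 minus mutant in Cy3) divided by 2. Tests were eBayes moderated and adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Both components, the gene lists and the rule for named genes were fixed before the data were examined. The rule took every crystallin with a tested probe, and per side up to 12 genes with the largest coefficient among probes past the threshold that had 1 symbol and the same sign on at least 80% of arrays. It also took up to 4 members past the threshold of each fixed list. Capn5, Capn1, Sc5d, Srebf2, Mbp, Atf4, Acta2, Cplx1, Atf3, Cox7b, Myh1 and Irf7 fall outside that rule and were chosen after their values were seen. The 34 gene lists covered crystallins, calcium handling, cell types and regions of the brain, tissues near it, and stress and housekeeping pathways. Lists with at least 3 probes were tested with camera on the moderated statistics, with a preset correlation of 0.01 and, as an alternative, 1 estimated from residuals.

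The model was tested on simulated data with 8058 probes, of which 200 were changed. In the dye-switching component it recovered 35.2% of probes changed by 0.3, 82.8% of those changed by 0.6 and 93.8% of those changed by 1.2, and 7.3% of its calls were unchanged probes. In the shared component it recovered 31.9%, 70% and 97.2% at these sizes, and 3.6% of its calls were unchanged. The simulated noise had a random sign drawn separately for each probe and array. These shares therefore hold for arrays that do not deviate together, which was not so here at the called probes. Alternatives were other centring, scaling, filters, weights and variance models, no dye term, averaged probes, an ordinary test per probe, resampled arrays, and each array left out in turn. Robust regression, values limited to between -2 and 2, and leaving out arrays 9 and 10 together were added after the data had been seen. Whether arrays close in accession order deviated together was checked after the data had been seen, in runs of 4 arrays. Such runs were then used as a random block, and as 1 value each, in alternatives added after the data had been seen. Figures were drawn with matplotlib 3.10.9.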

Results

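The series compared brain RNA of mice homozygous for O377, a mutant line carrying an altered allele of the crystallin gene Crybb2, with brain RNA of wild-type mice. Crybb2 encodes beta-B2-crystallin, a structural protein of the eye lens, and the title of the series asks about its expression in the brain. The mutant channel held RNA of 5 numbered brains, and the other channel held 1 pool of 4 wild-type brains. There were 15 arrays with 2 colours each. Mutant RNA carried Cy5 on 7 arrays and Cy3 on the other 8. Between 7843 and 10515 of 20205 probes had a value per array, and 8058 probes had a value on at least 4 arrays of each dye orientation and were tested. The values are log ratios, taken as log2, whose direction is not stated. They could run mutant over wild type or Cy5 over Cy3. Each probe was therefore split into a shared component, with 1 sign in both orientations, and a dye-switching component, whose sign turns with the dyes. The dye-switching component is positive where values were above 0 with mutant RNA in Cy5 and below 0 with mutant RNA in Cy3. It is the genotype difference, positive meaning higher in the mutant, if values run Cy5 over Cy3. It is the dye effect if they run mutant over wild type, and then the shared component is the genotype difference.

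The first comparison asked whether Crybb2 RNA itself differed between mutant and wild-type brains. The Crybb2 probe showed no difference past the threshold in either component. Its mean log ratio was -0.01 ± 0.30 (SD, n = 7 arrays) with the mutant in Cy5 and 0.01 ± 0.26 (SD, n = 8 arrays) with the mutant in Cy3. The 15 array values ran from -0.54 to 0.43. The dye-switching component of Crybb2 was -0.01, with a 95% confidence interval from -0.17 to 0.15 and a limma adjusted p of 0.982, and its shared component was 0.00 ± 0.07 (SE), adjusted p = 0.998. Where the probe lies relative to the altered part of the gene is not given in the sources used here, so this value checks neither the labels nor the allele.

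Other crystallins, which are lens proteins or their relatives, were also measured on these brain arrays. Of 19 genes in the crystallin list, 7 had a tested probe: Crybb2, Cryba1, Cryba2, Crygb, Crygc, Crygd and Crygs. None passed the threshold, over all probes or adjusted over the list alone. The dye-switching components ran from -0.11 ± 0.07 (SE) for Cryba1 to 0.03 ± 0.07 for Crygd. In the shared component Cryba2 stood at 0.24 ± 0.16 and Crygd at 0.15 ± 0.07, and the list median was 0.13. The camera test of the list in that component gave an unadjusted p of 0.0289 and an adjusted p of 0.405 over 28 lists, and adjusted p = 0.776 with an estimated correlation.

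The second comparison asked which genes stood out in the dye-switching component, which is the genotype difference only if values run Cy5 over Cy3. There, 52 probes passed the threshold, 27 on the positive side and 25 on the negative side. The largest was Capn3, a calcium-dependent protease, at 1.72 ± 0.12 (SE, n = 15), which is 3.29-fold, limma adjusted p = 4.87e-07. The largest negative value was that of Nt5c2, a cytosolic nucleotidase that acts on purine nucleotides, at -1.17 ± 0.09, a 2.24-fold difference in the opposite direction, adjusted p = 8.22e-07. Both kept their side on 15 of 15 arrays. The coefficients of the 52 probes were between 0.26 and 1.72 in size, and 19 exceeded 1.5-fold (0.58). All 52 had the same turned sign on at least 80% of their arrays, and 24 on every array. The 52 probes included 33 with 1 gene name, 3 with several and 16 with none. Without array 11 the negative side held 16 probes, and array weights raised the total to 81. The labels tie no array to an animal, and 15 arrays drew on 5 mutant brains, so these p-values are too small as tests of animals, the more so as arrays close in accession order deviated together at these 52 probes (permutation p = 0.00021). With 1 value per run of 4 arrays in that order, an alternative chosen after the data were seen, 2 probes passed, Capn3 (adjusted p = 0.00763) and Nt5c2 (adjusted p = 0.0212). With these runs as a random block, 53 passed at the correlation over all probes and 26 at that of the called probes. The wild-type pool is 1 control sample, so the spread of the control is left out.

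**Figure D1:**
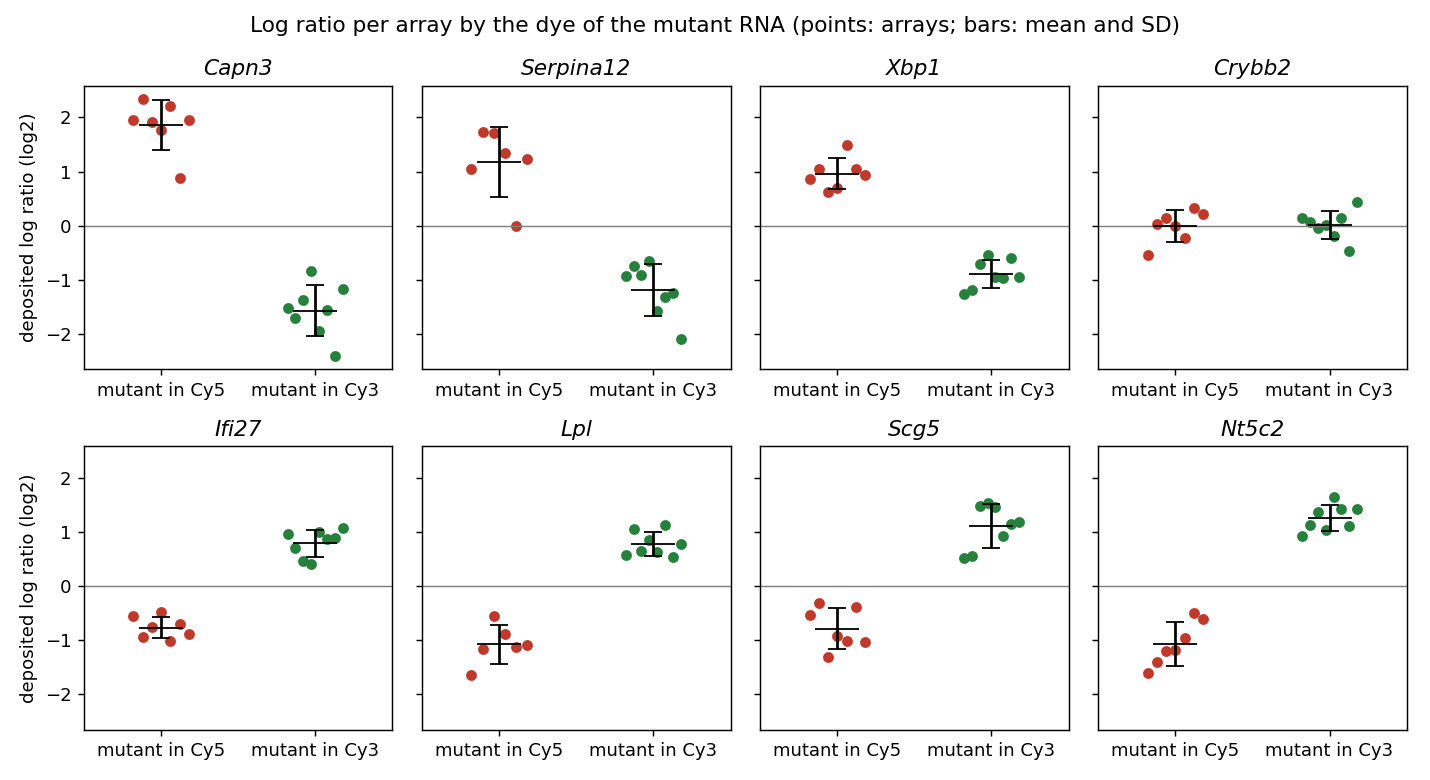
Deposited log ratio (log2) of 8 genes on each array, by the dye of the mutant RNA (7 arrays with the mutant in Cy5, 8 in Cy3); points are arrays, and bars are the mean and SD. Capn3 values lie at 0.89 or above with the mutant in Cy5 and at -0.85 or below with the mutant in Cy3, Nt5c2 turns the other way, and Crybb2 values lie around 0 in both.

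On the positive side, among probes with 1 gene symbol, Capn3 was followed by Serpina12, an adipokine of the serine protease inhibitor family, at 1.18 ± 0.14 (SE), adjusted p = 0.000176, on the positive side on 13 of 14 arrays. Nedd4l, a ubiquitin ligase, was at 0.95 ± 0.13, adjusted p = 0.00455 by limma, with values on 9 arrays. Xbp1, a transcription factor of the unfolded protein response, was at 0.93 ± 0.07, adjusted p = 2.02e-06, on 15 of 15 arrays. Rab9, a small GTPase of transport from late endosomes to the Golgi, was at 0.76. Atp5g2, a subunit of mitochondrial ATP synthase, was at 0.66. Yeats4, a chromatin reader, was at 0.63. The growth factor Mdk (midkine) was at 0.53, the mitochondrial ribosomal protein gene Mrpl48 at 0.51 and Zswim7 at 0.39. The adjusted p of these last 6 genes was at most 0.0136. S100a5, a calcium-binding protein of the S100 family, was at 0.88 ± 0.17, adjusted p = 0.0372. It missed the threshold without any 1 of arrays 2, 4, 6, 9, 10, 11, 12 or 13 (adjusted p from 0.0532 to 0.083). Dclk1, a kinase that binds microtubules, was at 0.61 ± 0.11 on 1 probe, adjusted p = 0.0177. Its other tested probe was at 0.14 ± 0.05, unadjusted p = 0.0166, and the mean of both probes gave 0.36.

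On the negative side, among probes with 1 gene symbol, Nt5c2 was followed by Scg5, a neuroendocrine chaperone of a prohormone convertase, at -0.95 ± 0.10 (SE), adjusted p = 4.22e-05, on 15 of 15 arrays. Lpl, the lipoprotein lipase, was at -0.93 ± 0.08, adjusted p = 7.9e-06, on 14 of 14 arrays. Ifi27, an interferon-induced gene, was at -0.78 ± 0.06, adjusted p = 2.7e-06, on 15 of 15 arrays. Smim7 was at -0.61, and Babam2, a member of a deubiquitinating complex in DNA repair, was at -0.58. Neat1, the long noncoding RNA of paraspeckles, was at -0.45. Pigf, of glycosylphosphatidylinositol anchor synthesis, was at -0.44, and the tetraspanin Tspan17 at -0.40. The adjusted p of these last 5 genes was at most 0.00497. The chemokine Ccl27a was at -0.47, adjusted p = 0.000426. Tap1, a peptide transporter of antigen presentation, was at -0.64 ± 0.13, adjusted p = 0.0372, on 12 of 15 arrays. It missed the threshold without any 1 of arrays 2, 3, 4, 9, 10, 11, 12, 13, 14 or 15 (adjusted p from 0.0666 to 0.0809). Thy1, a neuronal surface glycoprotein, was at -0.53 ± 0.11, adjusted p = 0.0276, and missed it without any 1 of arrays 1, 2, 3, 4, 9, 11 or 12 (adjusted p from 0.0505 to 0.0622).

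The means of some named genes were unequal in size in the 2 dye orientations, though none passed the threshold in the shared component. Of 25 named genes past the threshold, 3 had an unadjusted p under 0.05 in the shared component. Of all tested probes 9.5% did, so a count of 3 sets these genes little apart. Ccl27a averaged -0.77 with the mutant in Cy5 and 0.17 with the mutant in Cy3 (shared p = 0.000175), Tap1 -0.32 and 0.95 (p = 0.0324), and the nuclear receptor gene Nr4a1 0.19 and -0.46 (p = 0.0401). S100a5 averaged 0.62 and -1.15 and Nedd4l 0.72 and -1.19, with larger p in the shared component (0.154 and 0.089).

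**Figure D2:**
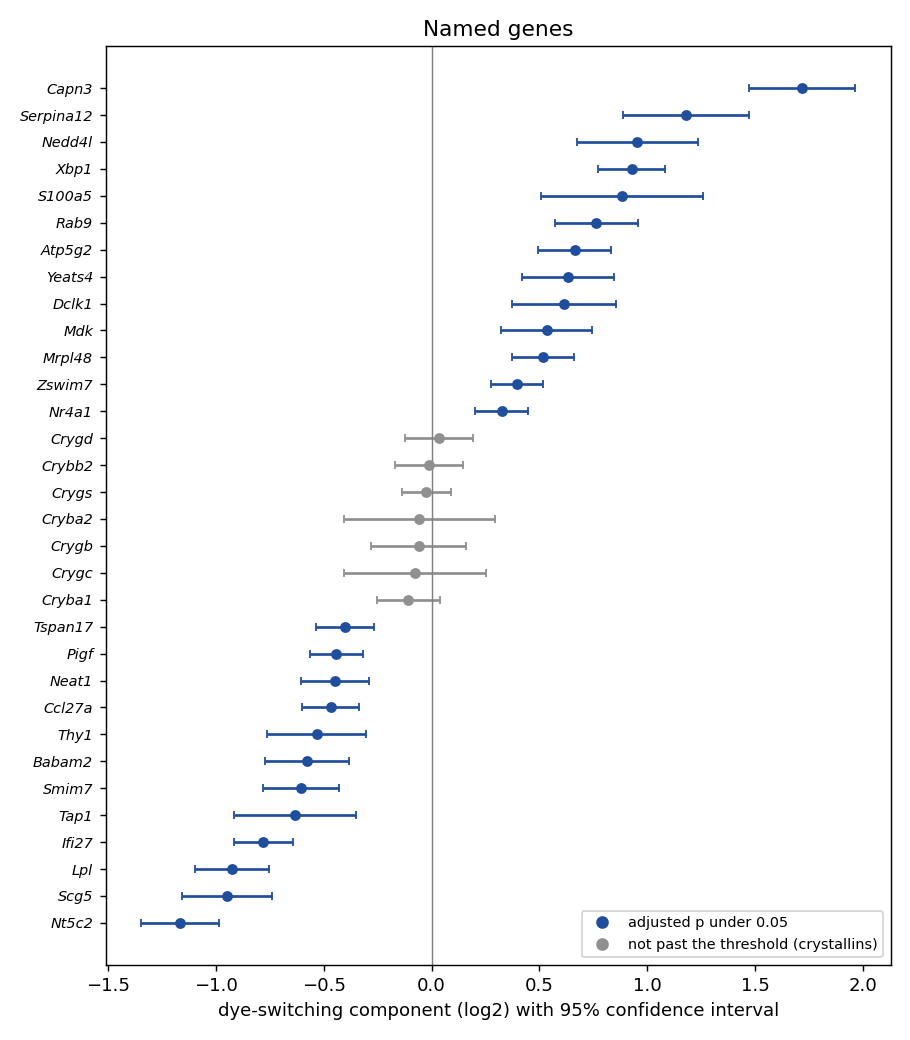
Dye-switching component (log2) of the named genes with its 95% confidence interval. Blue marks 25 genes past the threshold and grey the 7 crystallins; Capn3 (1.72) and Nt5c2 (-1.17) are the outermost, and all crystallin intervals include 0.

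None of the gene lists fixed in advance passed the threshold as a group in the dye-switching component. Of 34 lists, 28 had at least 3 tested probes. In camera, 0 lists passed the threshold, and 2 had an unadjusted p under 0.05. List medians ran from -0.09 (skeletal muscle) to 0.10 (cholesterol synthesis). Cholesterol synthesis, with 7 genes tested, had the smallest adjusted p, 0.23, and adjusted p = 0.264 with an estimated correlation. All 7 of its probes lay on the positive side, from 0.03 for Srebf2 to 0.18 for Sc5d, and none passed singly. The other was the cytosolic ribosome, with a median of -0.02 over 28 probes and adjusted p = 0.644, or 0.501 with an estimated correlation.

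Single list members passed the threshold without the rest of their lists. In calcium handling and calpains, Capn3 was the only 1 of 24 tested probes to pass, also adjusted over the list alone. Its relatives Capn5 (0.15, adjusted p = 0.282) and Capn1 (0.43, adjusted p = 0.461) did not. That list had a median of -0.04 but a mean of 0.07 and a positive camera sign. Among immediate early genes, 1 of 7 probes passed, both over all probes and adjusted over the list alone: Nr4a1, a nuclear receptor induced by activity, at 0.32 ± 0.06 (SE), adjusted p = 0.0105. Here too the list median (-0.05) and mean (0.02) had opposite signs. In the unfolded protein response, Xbp1 was the 1 of 7 probes that passed, and 2 passed adjusted over the list alone, Xbp1 and Atf4. Atf4, a stress-response transcription factor, was at -0.28, opposite to Xbp1. The median was -0.06 and the mean 0.06.

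Markers of cell types and brain regions showed little. In the pan-neuronal list Thy1 was the 1 of 12 probes past the threshold, also adjusted over the list alone, with a list median of 0.01, a mean of -0.06 and a negative camera sign. The myelin gene Mbp was at -0.22 (adjusted p = 0.419) on 1 probe and -0.03 on another. Adjusted over the list alone, 1 further probe passed in each of 2 lists, the smooth muscle actin gene Acta2 (0.21) among endothelium and pericyte genes and the synaptic gene Cplx1 (-0.28) among synaptic vesicle genes. No probe passed over all probes among markers of astrocytes, oligodendrocytes, microglia, endothelium, choroid plexus, meninges, pituitary, skeletal muscle, cerebellum, striatum, hippocampus and cortex, or among glutamate, GABA and hypothalamic peptide genes. The fixed lists for heat shock, oxidative phosphorylation, proteasome, glycolysis, oxidative stress and cell cycle had no probe past the threshold either. Atp5g2, the ATP synthase subunit gene that passed (0.66), was not among the probes of the oxidative phosphorylation list. Lists for the olfactory bulb and sex-linked genes had 0 tested probes, those for erythrocytes and photoreceptors 1 each, and those for the lens and for neighbours of Crybb2 had 2 each, so they were not tested as groups.

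In the shared component, 0 probes passed the threshold in limma, with a smallest adjusted p of 0.288, that of Ccl27a at -0.30 ± 0.06 (SE). At an unadjusted p under 0.05 there were 765 probes, 9.5% of those tested, beside 771 (9.6%) in the dye-switching component. With robust regression, chosen after the data were seen, 107 probes passed in the shared component and 204 in the dye-switching component. Of 28 lists, 0 passed in camera and 2 had an unadjusted p under 0.05, the crystallins and oxidative phosphorylation (median 0.07 over 24 probes, p = 0.0152, adjusted p = 0.405, or 0.709 with an estimated correlation). Adjusted over the list alone, 3 probes passed, the stress gene Atf3 (0.24) among immediate early genes, the respiratory chain gene Cox7b (0.32) and the myosin gene Myh1 (-0.20) among skeletal muscle genes.

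**Figure D3:**
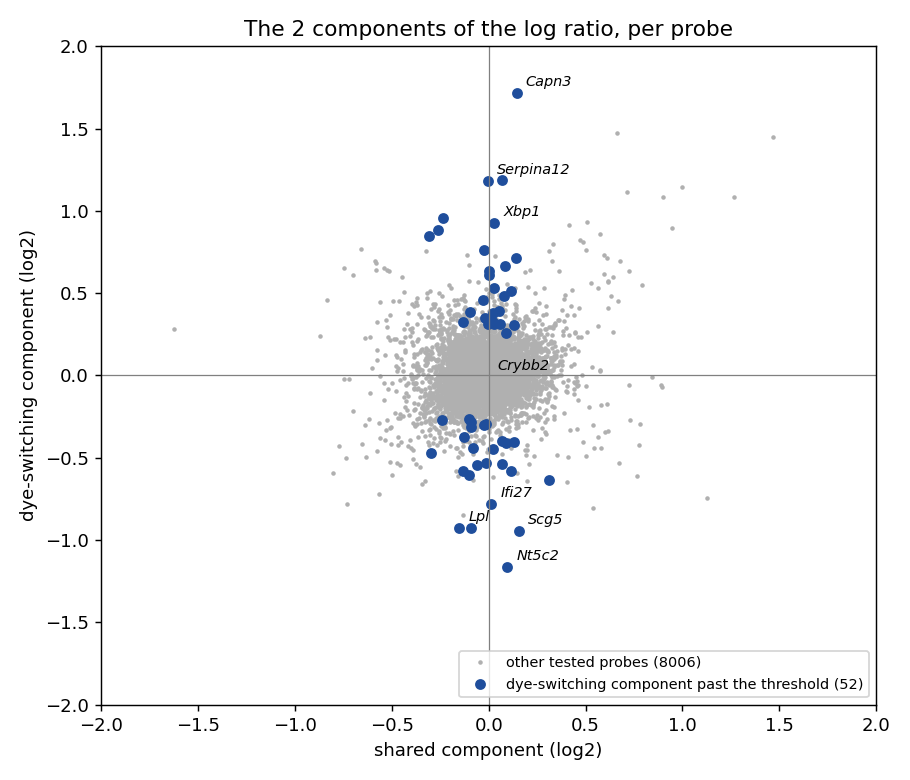
Shared component (horizontal, log2) against dye-switching component (vertical, log2) of each tested probe. The 52 probes past the threshold in the dye-switching component (blue) spread along the vertical axis from Nt5c2 (-1.17) to Capn3 (1.72), and the other 8006 probes are grey.

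The direction of the log ratio was not settled by the values. Rank correlations over the tested probes averaged 0.086 between arrays of the same dye orientation (from -0.118 to 0.351). Between arrays of opposite orientation they averaged -0.002 (from -0.25 to 0.166), so arrays shared little. Before the data were examined, mutant over wild type was held the more likely direction, since the mutant is always the second channel. The usual convention of Cy5 over Cy3 makes the dye-switching component the genotype difference, with Capn3, Serpina12 and Xbp1 higher and Nt5c2, Scg5 and Lpl lower in the mutant. That reading was preferred only after the counts of 52 and 0 had been seen. It is at most likely, and under the other reading these genes differ by dye and no gene passed for genotype. No 2 arrays shared a value, and the highest Pearson correlation between arrays, over all probes with values, was 0.135, so each array was counted once.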

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

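The test on extreme single values in this part was chosen after the result was seen. Within each dye orientation, 68 sets of array values were checked, of the named genes, the number of measured probes and the interquartile range. Of these, 2 held an array far from the others. Chance gives about 1 in 20, so this count is not above chance. Capn3 stood at 0.888 on array 10 with the mutant in Cy5, where the next lowest value was 1.77. Yeats4 stood at 1.58 on array 13 with the mutant in Cy5, where the next highest was 0.679.

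The dye-switching component held 52 probes past the threshold, led by Capn3, Nt5c2, Xbp1 and Ifi27. Of 100 splits of the arrays into 7 and 8, 1, the real split, gave as many, with 0 in the highest of the others. This argues against a chance split only if arrays are exchangeable. Arrays close in accession order deviated together at these probes, and random splits break such runs up, so chance at the level of runs was not excluded. The spread between animals was not tested, and only 2 probes, Capn3 and Nt5c2, passed with 1 value per run of 4 arrays. When each probe lost the array most in its favour, 37 of 52 still passed, so these did not rest on that 1 array. The removal pulls each coefficient toward 0 and leaves fewer values, so calls can be lost without an extreme value. Whether extreme single values account for the lost calls was therefore not decided. A dye effect of single probes, which applies if the ratios run mutant over wild type, remains open. Clustering of called genes along chromosomes would speak against it and was not found. There were 5 pairs within 5 Mb of each other, against a mean of 3.45 in random draws (permutation p = 0.26). Genes that differ by genotype need not lie close together either, so this result cannot tell the 2 readings apart. The other tested probes of called genes, of Dclk1 and Mettl1, lay on the called side in 2 of 2 cases (exact one-sided sign test p = 0.25, the smallest it can give), which cannot decide. A difference between mutant and wild-type brain RNA, as the design sets out, is the likely reading if the ratios run Cy5 over Cy3, and it cannot be told apart from the dye effect here.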

How the results depend on the processing

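Robust regression, values limited to between -2 and 2, the fit without arrays 9 and 10, and the fits with runs of 4 arrays in accession order were chosen after the data had been seen. In the dye-switching component the count of 52 probes (27 positive, 25 negative) rose to 81 with array weights (41 negative) and to 204 with robust regression (95 positive, 109 negative), which kept all 52. The shared component rose from 0 to 107 with robust regression and stayed at 0 under all other alternatives run. The cause of these changes was not tested. With runs of 4 arrays as a random block the count was 53 at the correlation over all probes (0.021 for values as deposited, -0.003 with the sign turned). At the correlation of the called probes themselves (0.232, sign turned), which was taken from probes chosen for their differences, it fell to 26 (13 positive, 13 negative). With 1 value per run, 4 values per probe at most and 7824 probes, it fell to 2 (1 positive, 1 negative), Capn3 and Nt5c2. The smaller number of values lowers the power there, and the labels do not say what the runs are. Averaged probes, with fewer tests, gave 37. That fit held only probes with 1 gene symbol, as 33 of the 52 had, so its count is not comparable with 52. Other alternatives with all arrays gave 45 (values on at least 2 arrays per dye orientation) to 69 (probes measured on all 15 arrays). Without arrays 9 and 10 the count was 53, of which 36 were among the 52. Leaving out 1 array gave 36 to 49 probes, 19 to 28 of them positive and 16 to 24 negative. The lowest total and the lowest negative count were those without array 11. In every alternative with list tests, 0 gene lists passed in either component. Lists were not tested with the ordinary test per probe or with resampled arrays. Of 25 named genes past the threshold, 17 stayed past it with the block at the correlation of the called probes. There Mdk and Nr4a1 (adjusted p = 0.15 each), Babam2 (0.0929), Neat1 (0.0692), Dclk1, S100a5, Tap1 and Thy1 missed it. With 1 value per run, 2 stayed past it (adjusted p up to 0.755). In every other alternative that tested them, 21 stayed past it. None changed sign in any. The other 4 were Dclk1 (adjusted p = 0.0509 in the ordinary test), S100a5 (12 of 27 alternatives missed, adjusted p up to 0.132), Tap1 (15 of 28, up to 0.13) and Thy1 (9 of 28, up to 0.0854). Nedd4l, among the 21, was tested in only 22 of these alternatives. It had 4 values with the mutant in Cy5, so fits without 1 of those arrays left it out, and its call was not checked there. Of the named genes past the threshold, those whose value in a single dye orientation lay over 1 SD from the value reported were Nedd4l at 1.19 (mutant in Cy3, sign turned) and Ccl27a at -0.77 (mutant in Cy5) or -0.17 (mutant in Cy3, sign turned). The cerebellum list median moved to -0.13 without array 9. Probe signals over background were not analysed here, so dim probes could not be set apart.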

Other observations

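The tests in this part were chosen after called genes had been seen, except that the list of unfolded protein response genes was fixed before. Called genes came from most chromosomes. Chromosomes 2 and 19 held 4 each, of 344 and 144 tested genes, and Crybb2's own chromosome 5 held 1 (Babam2) of 297. Of 5 pairs of called genes within 5 Mb of each other, 2 shared a side and 3 did not. Nr4a1 (0.32) and Atp5g2 (0.66) shared the positive side on chromosome 15, and Serpina12 (1.18) and Ifi27 (-0.78) on chromosome 12 were opposed.

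Genes linked to Crybb2 that came along with the mutation are a candidate source of the differences. Of 33 called genes with a place in the reference, 0 lay within 20 Mb of Crybb2, against 2.35% of the 4292 other genes (one-sided Fisher's exact p = 1). A count of 0 allows a share of up to 9.09%. On other chromosomes lay 32 of the 33, which argues against linkage as the source of the differences as a whole. Linkage over a longer distance stays open for Babam2, since the share of called genes on chromosome 5 decides nothing for 1 gene (one-sided Fisher's exact p = 0.905), and probes without a place in the reference stay open too.

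Ifi27 and Tap1, both induced by interferon, lay on the negative side, and Irf7 stood at -0.85 without passing (adjusted p = 0.0957). A shift of the whole interferon list by about their size would need a median near -0.64 (Tap1). The 20 probes, these 3 included, had a median of -0.04, which argues against a shift that large. Its 95% interval, -0.12 to 0.01, took probes as independent, though the 17 probes besides these 3 come from 15 genes. Ifi27 and Tap1 were taken up because they passed, so this bounds only a shift as large as theirs. A smaller shift may have gone with them and stays open, since that interval reaches below 0. The other 17 probes had a median of -0.022, with 11 below 0 and 0 past the threshold (camera p = 0.75), and such a p was set beforehand as evidence against any group response. That bound was set aside, and the bound on the size was added, after these values had been seen, because the interval leaves room for a median of -0.12.

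Xbp1 was on the positive side, and an active unfolded protein response might accompany it. The other 6 genes of that list had a median of -0.075, with 4 below 0, away from Xbp1's side (camera p = 0.0456). Of these 6, only Atf4 (-0.28) passed adjusted over the list alone, so the evidence rests largely on 1 gene. The side of the group argues, if weakly, against its rise together with Xbp1. Whether Xbp1 itself differs by genotype or by dye is open.

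The components of different probes of the same gene were nearly uncorrelated across genes. Over 374 genes with more than 1 tested probe, the rank correlation between the first 2 probes, across genes, was 0.056 in the dye-switching component (permutation p = 0.279). In the shared component it was 0.009 (permutation p = 0.855), and genes are not independent replicates. Only 52 of 8058 tested probes passed, and noise in genes without a difference can give such values. The correlations therefore cannot show whether probes of a gene disagree.

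Arrays close in accession order deviated together at the called probes. In runs of 4 arrays in that order, the mean product of standardised residuals with the sign turned, over 14 pairs of opposite dye orientation, was 0.145 at the 52 called probes (permutation p = 0.00021) and -0.017 at the other 8006 (permutation p = 0.473). Thy1 with its sign turned lay between -0.15 and 0.09 on arrays 13 to 15, and Tap1 between -0.11 and 0.42 on arrays 5 to 8. Over the tested probes, arrays of the same dye orientation had a mean rank correlation of 0.2 within such runs (7 pairs) and 0.066 outside them (42 pairs). The labels do not say whether neighbouring arrays share an animal or a labelling batch, and a dye effect that differs between batches turns its sign in the same way, so the direction of the ratio is not settled by these values.

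The shared component also held more low p-values than sign changes of whole arrays gave. At an unadjusted p under 0.05 it had 765 probes, against a median of 398 and a highest of 727 in the others of 100 sign assignments. The dye-switching component had 771, against a median of 344 and a highest of 665 in the other splits. Both comparisons shuffle single arrays and break up the correlation of arrays close in accession order. That correlation can raise such counts by itself, so neither excess shows a component of the ratios. After adjustment, 0 probes passed in the shared component as reported, so no gene is named for this excess.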
